A study of Lactiplantibacillus plantarum with 3 samples.

How the data were processed

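The series measured transcripts of Lactiplantibacillus plantarum WCFS1, a lactic acid bacterium found on plant material and in the gut, after 10 min with 1.5 mM p-coumaric acid, a plant hydroxycinnamic acid, against untreated cells. Each of the 3 two-colour Agilent arrays carried RNA of a treated and an untreated culture, and the labels call the 3 arrays independent biological replicates. In replicate 1 the treated RNA was labelled with HyPer5, a red dye, and the untreated RNA with Cy3, a green dye. In replicates 2 and 3 the dyes were the other way round. The dye swap was therefore unbalanced, 1 array against 2, and whatever sets replicate 1 apart from the other arrays cannot be told apart from its dye orientation. Per the labels' protocols, cDNA was primed with anchored oligo(dT) primers, which is recorded here as stated.

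The deposited intensity values, the mean brightness of each spot and the median brightness of its local background in each channel, were written by Agilent Feature Extraction 10.7.3.1, per the file headers, and had not been normalized. The same files hold intensity values that Feature Extraction had background-subtracted and dye-normalized, per the file headers, and these served as an alternative. A further table deposited by the authors holds log2 ratios of treated over untreated per spot, for each array in 3 columns without a replicate number and for the arrays together. Per the file headers, the authors corrected the background by normexp with an offset of 50, normalized by loess within each slide and by quantiles between slides, and adjusted p-values by false discovery rate. The submitters' processing notes name limma. The p-values and false discovery rates of that table are the authors' own, and the authors' log2 ratios entered only an alternative.

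Each array held 15744 spots, of which 536 were controls or carried no locus and 15208 carried 9023 probes of 3046 loci, with a median of 3 probes per locus. Spots with a non-uniformity or population outlier mark in either channel were left out, which were 25.1% of the locus spots in replicate 1, 19.3% in replicate 2 and 5.40% in replicate 3. No locus spot was marked saturated. The background was corrected by normexp with an offset of 50, and log ratios were normalized by loess within each array, with control and outlier spots given no weight. The sign was turned so that every ratio was treated over untreated. Log2 ratios of spots were averaged per probe, and those of probes were averaged per locus. Probes were kept if most of their spots were well above background in the treated or in the untreated channel on at least 2 arrays, which kept 8172 probes and left out 851. Loci measured on at least 2 arrays were tested, 2913 in all, of which 109 were measured on 2 arrays, and 133 loci were not tested. The probes of a called locus disagreed in sign in 0.403% of called loci.

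Each locus was fitted with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) as a mean log2 ratio against 0, and p-values were adjusted by Benjamini-Hochberg over all loci tested, two-sided. A locus was called at an adjusted p under 0.05. The treated and untreated cultures are paired within an array through the ratio, and the precision is limited by the number of arrays. All 3 arrays lay on a single slide and no slide term could be fitted. Standard deviations are over arrays. The steps from probes to calls were tested on simulated data for 3 arrays and 2921 loci, of which 200 were changed: 70% of 100 loci changed 2-fold and 97% of 100 loci changed 4-fold were called, and 2.9% of the calls were false. The simulated noise was independent between loci and between arrays and held no dye effect, so these shares need not hold for the real arrays.

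The files give locus tags and do not pair them with gene names. The table of RefSeq genes that was used describes another strain of the species, and 0 of the 3046 loci matched it. Of 24 gene lists fixed before the data were examined, 23 were defined by gene symbols alone and could not be filled. The remaining list, phenolic acid metabolism, had been written with 11 locus tags. The names given to these loci were written down with the list, from general knowledge of this strain, and were not checked against a table. The list was tested with limma's camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and with fry as alternatives. Loci printed in at least 16 spots and tRNA loci were described as groups added after the data were seen.

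The loci named in the text were fixed by a rule before the data were examined: the members of the phenolic list, the 10 largest rises and the 10 largest falls among called loci with the same sign on all 3 arrays, and up to 4 members of each other list. Because the loci have no names in the files, the phenolic members are given, with the leading 2 rises outside that list and the leading 2 falls, and the others are summarised. Locus order was taken from the number in the locus tag, since no coordinates were used here. Alternatives covered the background correction and its offset, the normalization within and between arrays, the filter on dim probes, outlier spots, the median over probes, a dye intercept, a fit of separate channels without array pairing, eBayes with trend and robust settings, array weights, the authors' per-array values, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9.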

Results

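The transcript response of L. plantarum WCFS1 to p-coumaric acid was measured on 3 two-colour arrays, each a comparison of cells exposed to 1.5 mM of the acid for 10 min with untreated cells. Median spot brightness was 3983 in Cy3 and 1845 in HyPer5 on replicate 1, 4806 and 1617 on replicate 2, and 3077 and 1336 on replicate 3. Between 82.2% and 94.9% of the locus spots of a channel were well above background. The comparison asks which transcripts differed between treated and untreated cells, and it rests on 2913 loci.

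The transcript of lp_3665, the p-coumaric acid decarboxylase Pdc that converts p-coumaric acid to a vinylphenol, showed the largest rise of all tested loci. Its log2 ratio was 7.36 ± 1.29 (SD, n = 3), with a limma adjusted p of 0.00151. This mean includes replicate 1, on which the untreated signal was not well above background. Without replicate 1, on the arrays with untreated RNA in HyPer5, the log2 ratio was 6.62, a 98.1-fold rise (adjusted p = 0.00193). The neighbouring locus lp_3664, encoding PadR, the repressor of that decarboxylase, rose by 2.00 ± 0.18 (SD, n = 3; adjusted p = 0.00151), and the next locus, lp_3663, rose by 1.07 ± 0.19 (SD, n = 3; adjusted p = 0.00804). The pair lp_1424 and lp_1425, encoding the subunits HcrA and HcrB of a hydroxycinnamate reductase, rose by 3.86 ± 0.46 (SD, n = 3; adjusted p = 0.0011) and by 4.40 ± 0.26 (SD, n = 2; adjusted p = 0.00127). The lp_1425 value comes from replicates 2 and 3, because all 6 of its spots carried an outlier mark on replicate 1. On that array 3 of the 4 spots of lp_1424 and 4 of the 5 spots of lp_3663 carried a mark too. The replicate 1 values of lp_1424 and lp_3663 therefore rest on the few spots left.

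**Figure D1:**
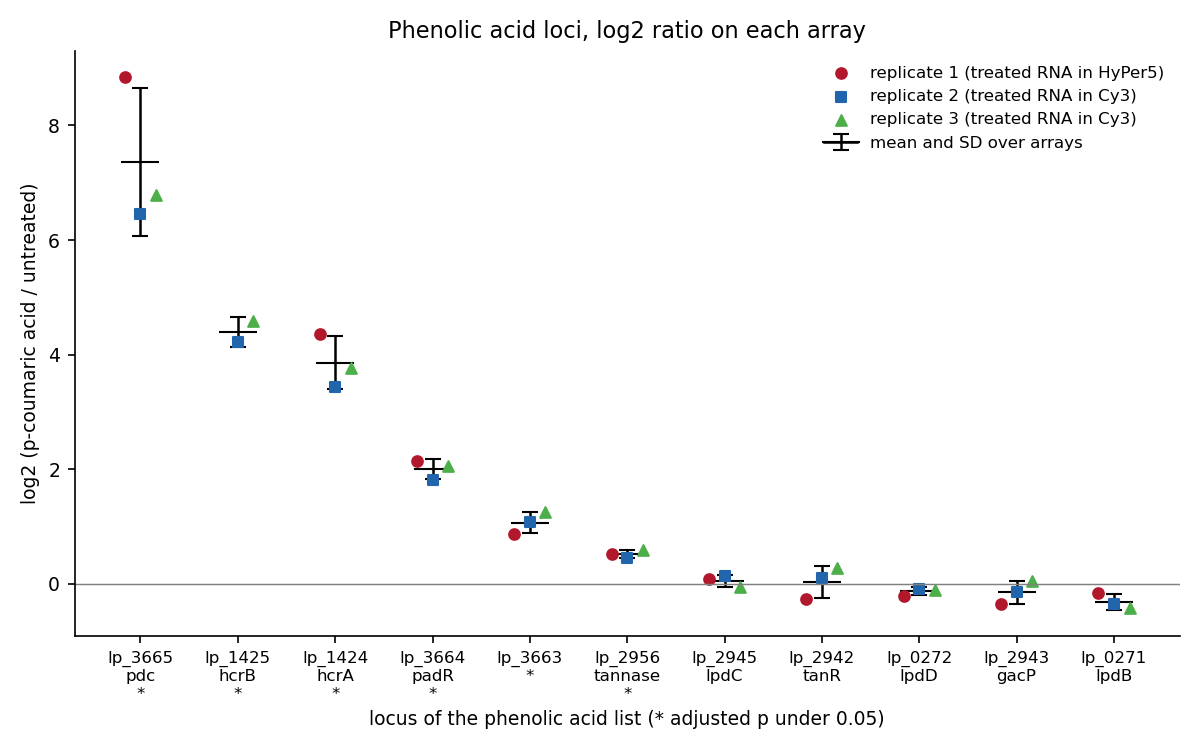
Log2 ratio of p-coumaric acid over untreated for the 11 loci of the phenolic acid list, with a point for each array and a bar for the mean ± SD over arrays. The 6 starred loci passed an adjusted p of 0.05, from lp_3665 at 7.36 to lp_2956 at 0.52, and the other 5 lay between -0.32 and 0.05.

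Of the 11 measured loci of the phenolic acid list, 6 rose, 0 fell and 5 were not called, and the count adjusted over the list alone was also 6. At an unadjusted p under 0.05, limma gave 6 higher and 1 lower. The list passed limma's camera in the upward direction (adjusted p = 0.00274, 1 list tested), with a median log2 ratio of 0.52 and a mean of 1.70. With an estimated correlation the list did not pass camera (p = 0.123, 10 members measured on all 3 arrays, without lp_1425). The estimate was -0.065, below the preset 0.01, so the higher p does not come from a larger estimated correlation. An estimate from 3 arrays is imprecise and does not show that the members were independent. By limma's fry, run on the same 10 members, the list moved upward on balance (adjusted p = 0.00144, 1 list tested). The tannase locus lp_2956, whose product hydrolyses gallotannins, had the smallest called rise, 0.52 ± 0.07 (SD, n = 3; adjusted p = 0.0374), and its call was lost under 5 alternatives. Its log2 ratio was then 0.42 with median centring (adjusted p = 0.0936), 0.79 with no normalization (adjusted p = 1) and 0.38 with no filter on dim probes (adjusted p = 0.07). It was 0.56 without replicate 2 (adjusted p = 0.163) and 0.49 without replicate 3 (adjusted p = 0.187). In untreated cells 98%, 66% and 80% of the lp_2956 spots were well above background on replicates 1, 2 and 3.

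The loci of gallate metabolism were not called. The gallate decarboxylase loci lp_0271 (LpdB), lp_0272 (LpdD) and lp_2945 (LpdC) had log2 ratios of -0.32 ± 0.13, -0.13 ± 0.07 and 0.05 ± 0.10 (SD, n = 3), with adjusted p of 0.134, 0.466 and 0.792. The gallate transporter locus lp_2943 (GacP) was at -0.15 ± 0.20 and the regulator locus lp_2942 (TanR) at 0.03 ± 0.27 (SD, n = 3), with adjusted p of 0.487 and 0.905. The 95% confidence intervals were -0.62 to -0.01 for lp_0271 and -0.48 to 0.19 for lp_2943. Signal was dim at lp_2943, where 68.6%, 37.3% and 64.7% of untreated spots were well above background on replicates 1, 2 and 3. At lp_2945 the share was 58% on replicate 2. A small change at these dim loci could have been missed. For lp_0271, lp_0272 and lp_2942 the share was at least 96% on each array. The lp_0271 locus was called lower with array weights (log2 ratio -0.36, adjusted p = 0.0331).

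The untreated level of the decarboxylase transcript was not well above background on replicate 1. There the untreated lp_3665 signal averaged 123 in Cy3, where the negative controls had a median of 111, and 0% of its 50 spots were well above background. The median local background of locus spots in that channel was 411.5, above this signal. On replicates 2 and 3 the untreated signal averaged 1199 and 1086 in HyPer5, with 100% of the spots well above background, against 265000 and 237000 in treated cells. The median local background in HyPer5 was 630.5 on replicate 2 and 427 on replicate 3. The log2 ratios on the 3 arrays were 8.84, 6.45 and 6.78, and the untreated signal was well above background on 2 of the 3 arrays. Those are the arrays with untreated RNA in HyPer5, so this difference in untreated signal cannot be told apart from the dye orientation. Whether the HyPer5 signal of these spots reflects untreated transcript alone was not tested, so the size of the rise is uncertain.

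Across all loci, 496 of 2913 (17.0%) were called, of which 285 rose and 211 fell. The balance of directions depended on the values used, with 334 higher and 331 lower from Agilent's processed signals and 292 higher and 325 lower from the authors' per-array values. A dye intercept gave 873 called loci and array weights 1056. At least 2-fold changes were called at 190 loci, 126 higher and 64 lower. Rises of at least 4-fold numbered 27 and falls 6, and rises of at least 8-fold numbered 15 and falls 1. A further 36 loci had mean ratios of at least 2-fold without being called, 27 of them lower in treated cells. Among called loci with the same sign on all 3 arrays, the 10 largest rises lay between 3.38 and 7.36, and 2 of them, lp_3665 and lp_1424, were members of the phenolic list; lp_1425, at 4.40, was measured on 2 arrays and is not among these 10. Outside the list the leading rises were lp_1261 at 4.62 ± 0.56 (SD, n = 3; adjusted p = 0.0011) and lp_0990 at 4.43 ± 0.11 (SD, n = 3; adjusted p = 0.000357), for which the files give no gene name. The 10 largest falls among these loci lay between -3.40 and -1.69. The lp_3256 locus had the lowest mean, -3.40 ± 2.28 (SD, n = 3; adjusted p = 0.0472), but its arrays read -4.54, -4.88 and -0.78, and its call was lost under 3 alternatives. Its log2 ratio was then -3.43 with a normexp offset of 0 (adjusted p = 0.0531), -3.40 with trend and robust eBayes (adjusted p = 0.116) and -2.83 without replicate 1 (adjusted p = 0.113). The lp_3015 locus followed at -2.45 ± 0.29 (SD, n = 3; adjusted p = 0.00147). The count of called loci was 751 without replicate 1 and 254 without replicate 3. With no within-array normalization 21 loci were called, and lp_3664, lp_3663, lp_2956 and lp_3015 were not among them. Their log2 ratios were then 2.54, 1.52, 0.79 and -2.09, where the median of all loci was 0.35. That median is not a shift shared by the arrays, whose own medians were -1.17, 1.32 and 0.98 on replicates 1, 2 and 3.

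**Figure D2:**
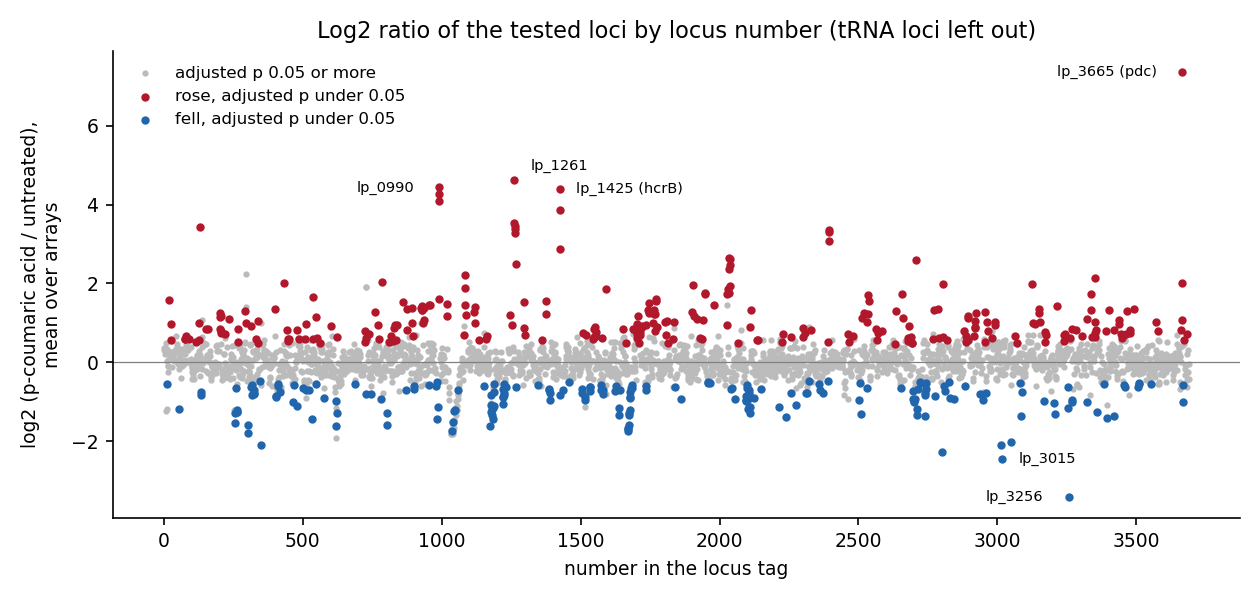
Mean log2 ratio of p-coumaric acid over untreated against the number in the locus tag, a point for each tested locus other than tRNA loci. Coloured points passed an adjusted p of 0.05 (285 higher in red, 211 lower in blue), and lp_3665 stands highest at 7.36.

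Of 13 measured tRNA loci 0 were called by limma and 1 was lower at an unadjusted p under 0.05, with log2 ratios between -0.59 and 1.18 and a median SD over arrays of 0.84, and limma's camera gave an adjusted p of 0.712 over the 3 groups added after the data were seen. Of the 12 loci printed in at least 16 spots, 2 rose (3 when adjusted over the list alone, all higher) and 0 fell (1 lower at an unadjusted p under 0.05), and the 2 were the decarboxylase lp_3665 and the tannase lp_2956. For this group camera gave an adjusted p of 0.429, and for its 6 members outside the phenolic list, of which 0 were called and 1 was higher at an unadjusted p under 0.05, also 0.429.

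The arrays of the same dye orientation were closer to each other than to the array of the opposite orientation. Pearson's r across loci was 0.831 between replicates 2 and 3, 0.649 between replicates 1 and 2, and 0.619 between replicates 1 and 3, where loci are not independent replicates. The same sign on all 3 arrays was found at 1544 of 2804 loci (55.1%). With no effect and independent arrays the share would be 25%, which leaves out any dye bias shared by replicates 2 and 3. A stretch of 22 loci numbered 1032 to 1056 had median log2 ratios of -2.16 on replicate 2 and -1.92 on replicate 3 but -0.28 on replicate 1. Of its loci 4 were called, among them lp_1038, one of the 10 largest falls. The mean over arrays had a median of -1.47 in the stretch, so some of the uncalled loci with at least 2-fold lower means lie there. Without replicate 1, all 22 were called. The same kind of disagreement was also found outside the stretch, at 43 loci in all with the 22 included.

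**Figure D3:**
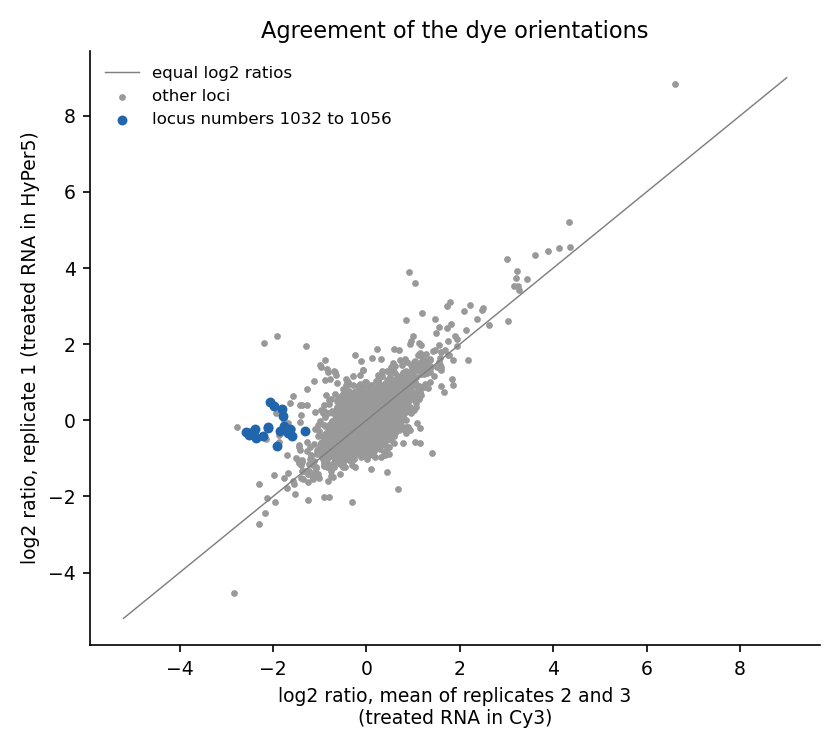
Log2 ratio on replicate 1 against the mean log2 ratio of replicates 2 and 3, which have the opposite dye orientation, a point for each locus measured on all 3 arrays. The 22 loci numbered 1032 to 1056, in blue, lie near 0 on replicate 1 and near -2.16 and -1.92 at the median on replicates 2 and 3.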

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

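The rise of lp_3665 kept its direction and call under all 17 alternatives that gave a value, at log2 ratios from 6.62 to 8.52; the filter on both channels left no probe of it. With no within-array normalization 21 loci were called (20 higher), all at least 2-fold, the same-sign count was 204, and the median of all loci moved to 0.35 from 0.01. The array medians were then -1.17, 1.32 and 0.98 on replicates 1, 2 and 3, opposite in sign between the dye orientations. These differences between arrays enter the spread of the loci in that setting, and ratios are relative to each array's centre. A dye intercept gave 873 called loci, with its error from replicates 2 and 3 alone, and array weights 1056. Leaving out a replicate gave from 254 called loci (without replicate 3) to 751 (without replicate 1). The other alternatives gave 421 to 695, with 175 to 276 at least 2-fold. The authors' per-array values gave 47.3% higher among called loci, against 57.5%. The cause of these shifts was not tested. Fewer arrays alone would not raise the count to 751. Replicates 2 and 3 were closer to each other than to replicate 1, so the spread is smaller without replicate 1. Any dye bias shared by replicates 2 and 3 also counts as treatment effect there, and the sources of their closeness cannot be told apart. The same-sign count cannot move with the settings of the fit. Over the 2 remaining arrays, the sign was shared at 2301 of 2883 loci without replicate 1, 1803 of 2829 without replicate 2 and 1867 of 2809 without replicate 3.

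Without the pairing by array, the separate-channel fit called 550 loci, 451 shared with the main analysis. The phenolic list passed under every alternative except the estimated correlation, under which 0 lists passed (p = 0.123). Over 28 other named loci, 471 of 502 values kept direction and side of the threshold, 20 calls were lost (12 with no within-array normalization), 1 was gained and 10 values changed sign, none of them at a called locus. These were lp_2942 at -0.019 with Agilent's processed signals, -0.082 with outlier spots kept, -0.042 with a dye intercept, -0.10 with the authors' values and from -0.087 to 0.18 leaving out a replicate; lp_2945 at -0.18 with median centring, -0.033 with outlier spots kept and -0.013 with the authors' values; and, with no within-array normalization, lp_0272 at 0.15 and lp_2943 at 0.017. Of the dimmest loci, 47 were not well above background in untreated cells on any array, and 94 in treated cells.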

Other observations

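The tests on shuffled locus order were chosen only after the patterns had been seen. Called loci lay in runs along the locus numbering, which was taken as gene order. There were 40 runs of at least 3 called neighbours of one direction, 25 higher and 15 lower in treated cells. Several of the large rises lay in such runs: lp_1261 began a run of 5 loci with log2 ratios from 3.28 to 4.62, lp_0990 lay in a run of 4 loci from 1.60 to 4.43, and the reductase pair lp_1424 and lp_1425 lay in a run of 3 loci from 2.88 to 4.40. The decarboxylase locus lp_3665 closed a run of 4 loci, from 0.83 to 7.36, that also held lp_3664 and lp_3663. A run of 3 loci numbered 2393 to 2395 had a median of 3.31, and a run of 6 loci numbered 2033 to 2038 a median of 2.41. The longest falling runs were 11 loci numbered 1670 to 1680, with a median of -1.27, and 10 loci numbered 2099 to 2108, with a median of -0.83.

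Runs of at least 3 held 163 of the 496 called loci, and at most 33 in any of 1000 shuffled orders. Spots of neighbouring called loci were printed no closer together than those of random pairs of loci (median distance ratio 1.01), which argues against print position as the source. Identical probes cannot have made the runs, because 0 probes were shared between any loci. The 0% of the 123 neighbouring pairs in runs that shared an identical probe was therefore fixed in advance. Probes that are similar without being identical were not compared. The runs are consistent with neighbouring loci being transcribed together, as a hypothesis found and tested on the same data. Operon maps and the strand of the loci were not used here, so the loci of a run need not share a transcript.

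In the stretch of 22 loci numbered 1032 to 1056, all 22 had log2 ratios of -1 or lower on replicates 2 and 3, and 0 had on replicate 1, with a median gap of 1.91 between replicate 1 and the mean of the others. The criterion was a mean of -1 or lower on replicates 2 and 3 and a gap of at least 1. It was met by 43 loci in all, so the pattern was not confined to the stretch. A gap of at least 1 was found at 116 loci, and a gap of -1 or lower at 34. The median gap over the stretch was 2.46 with median centring in place of loess, and 1.87 after the trend with probe G+C and T content was removed, which argues against loess and against base composition as its whole source. The 64 other loci of like brightness had a median gap of 0.47 ± 0.88 (SD over loci). Bias of single probes, falling anywhere in the order, would give runs like those of 1000 shuffled orders, at most 3 such loci against 22 observed. Bias that ignores the order is therefore an unlikely source. The shuffles cannot test a bias that follows a property shared by neighbours, such as brightness. A difference between the cultures of replicate 1 and the others, and a dye effect on the transcripts of this stretch, cannot be told apart, because replicate 1 is the single array of its orientation.

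With the signs of the 3 arrays reassigned, 1 of the 4 distinct assignments gave as many called loci as the real one, namely the real one itself, with 496 called loci against at most 0 in the others. The assignment that turns replicate 1 is the contrast of the dyes, green over red. Only 4 assignments exist, which are too few for a share under 0.05.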
